A study of Mus musculus with 2 samples.

How the data were processed

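The study measured H3K4me3 by chromatin immunoprecipitation and sequencing (ChIP-seq). H3K4me3 is trimethylation of a lysine near the start of histone H3, a mark found mainly at the transcription starts of genes that are active or poised. Per the labels, the tissue was midbrain of mouse embryos of the B6NCrl strain at embryonic day 11.5 (E11.5), dissected and pooled from males and females, with 109 embryos in replicate 1 and 88 in replicate 2. The labels call the 2 samples biological replicates, and both belong to 1 group. No control library and no other tissue or stage was analysed here, so no comparison between conditions was made.

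The files used were 4 peak lists on the mouse genome build mm10, per the file headers. These were a list for each replicate, a list called on the pooled replicates, and a list of replicated peaks. Every one of the 21414 replicated peaks was an entry of the pooled list, which was checked by position and values. Not all of them were seen in both replicate lists. A peak of both lists overlapped 95.23% of them, a peak of replicate 2 only 4.22% and of replicate 1 only 0.54%. Per the file headers, a replicate's peaks were made from that replicate's alignments and further files whose kind was not named. The aligner, the peak caller and its settings, and the rule that made a pooled peak a replicated one are not given in the sources used here. For each peak the authors deposited an enrichment value, which was taken as a linear ratio (fold over background) from its range and its place in the peak format. The authors also deposited −log10 p and −log10 q values for each peak. The lists begin just above a −log10 p of 2, so they hold weak peaks as well as strong ones. Enrichment and q were the authors' own values per peak, and were used only to describe, rank or filter peaks within a list. Their scale may differ between lists. The number of reads behind each list is not part of the files, so the depth is unknown, and peak numbers are what the files show. A gene without a peak lay under the caller's threshold, which does not show that the mark was absent.

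Peaks were compared with the GENCODE M21 annotation of GRCm38, the assembly named mm10 by the authors. Chromosomes 1 to 19, X and Y held 21853 protein-coding genes with 54361 distinct transcript starts. A gene was called marked when a replicated peak lay within 1 kb of any of its starts. Peaks were merged into domains across gaps of up to 1 kb, and a gene's breadth was the length of the widest domain that reached within 1 kb of a start. A domain that reached several genes counted for each. Values are those of the replicated list, and the replicate lists give the mean ± SD (n = 2), which need not centre on the replicated value because the lists were called separately. The CpG class of a gene came from 500 bp windows within 1 kb of its starts. High meant a window with an observed to expected CpG ratio of at least 0.75 and at least 55% GC. Low meant no window at a ratio of 0.48 or above, and the remainder were intermediate. A start region was called shared when at least 50% of the 36-mers within 500 bp of a gene's starts were found again in another, separate start region of a protein-coding gene. The rest of the genome was not searched. Coordinates are 1-based on mm10.

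The gene lists, tests, named-gene rule and alternatives described here were chosen before the data were examined. There were 27 gene lists, covering brain regions, neural and other cell types, gene families with known regulation, and families unlikely to be used in embryonic midbrain. They held 2114 genes, of which 17 were in more than 1 list, and 1 of the 18 erythroid symbols had no entry in the annotation. Each list's marked share was set against all other protein-coding genes with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 27 lists, and its result is given as an adjusted exact p. Median breadth was compared with that of all other marked genes by a two-sided permutation test with 100000 resamples, for the 17 lists with at least 10 marked members, with adjustment over those lists. The smallest p that these permutations can give is 1e-05. Genes are not independent replicates, so these p-values describe gene sets in this tissue and carry no error between animals. Intervals for shares are 95% Wilson intervals and cover counting error only. The p-values that fell below 1e-300 are given as such. Replicate lists were compared by overlap of at least 1 bp, against 20 shuffles of the peaks within their chromosomes. Distal meant more than 5 kb from any annotated start for peaks, and more than 5 kb from a protein-coding start for domains.

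Genes were named by a fixed rule. It took the 25 genes with the widest domains present in both replicate lists, with the gene nearest the centre of a shared domain. For each list it took the 3 members with the widest domains and the first 2 in alphabetical order with no peak in any of the 4 lists. It also took the 5 widest domains beyond 5 kb of a protein-coding start, the Y-linked list and Xist, and the 3 highest and 3 lowest ratios of replicate breadths. Genes named outside this rule are said to have been chosen after their values were seen.

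The alternatives replaced the replicated list by the pooled list or by either replicate, kept only peaks with −log10 q of at least 10 or the 50% with the highest enrichment, and moved the start window to 500 bp or 2 kb. Others used only the 5′ end of each gene, merged no peaks or merged across 3 kb, or restricted the genes to high-CpG promoters. In the X chromosome comparison, olfactory and vomeronasal receptor genes were left out on X and autosomes alike. Further alternatives took p from 10000 circular shifts along the gene order, or changed the overlap that counted as shared. All of them were run.

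The procedures were tested on simulated data. All 500 genes given planted domains were called marked with the exact breadth, among 21853 genes. All 20000 peaks kept from a list of 28524 were found again by the overlap step, which checks the step only, as both came from the same list. Of 200 random lists of 20 genes, 2% had an unadjusted p under 0.05 for the marked share and 2.5% for breadth. Random genes seldom lie side by side, and breadths were shuffled among marked genes for the breadth test. These rates therefore do not cover lists of neighbouring genes that share domains, such as histones. Lists with 19 of 20 members marked were recovered in 100% of runs, but each run tested nearly the same counts, so this outcome was fixed in advance. Lists widened 1.5 times were recovered in 92.5% of runs, and lists widened 2 or 3 times in 100%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.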

Results

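H3K4me3 was profiled by ChIP-seq in the midbrain of mouse embryos at E11.5, a stage when most midbrain cells are dividing progenitors and the first neurons have formed. The 2 biological replicates were pools of 109 and 88 embryos of both sexes. Replicate 1 had 28535 peaks and replicate 2 had 26215 (27375 ± 1641, SD, n = 2). Their median widths were 776 and 1043 bp, and they covered 30.6 and 33.3 Mb of the genome. The replicated list, used for all gene values, held 21414 peaks with a median width of 1336 bp over 32.3 Mb. Its median enrichment, as deposited by the authors, was 24.3, and 79.5% of its peaks had a −log10 q of at least 10. The number of reads is unknown.

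The replicates marked nearly the same genes. Of the protein-coding genes marked in either replicate list, 98.1% were marked in both, which was 14012 genes, while 106 were marked only in replicate 1 and 167 only in replicate 2. Breadth at these genes ranked alike in the lists, with a Spearman rho of 0.924 across genes. Peak by peak the lists differed more. Of the replicate 1 peaks, 82.9% (95% interval 82.4 to 83.3) were overlapped by a replicate 2 peak, and 80.3% (79.8 to 80.8) of replicate 2 peaks were overlapped in return. Shuffled peaks overlapped in 2.38% of cases on average, and the 2 lists shared 79.3% of the bases covered by either. Across the 23646 overlapping peaks of replicate 1, enrichment correlated with that of replicate 2 with a rho of 0.788 and a Pearson r of 0.794 on the log2 scale. The peaks seen in 1 list only were narrow and weak. The 4889 such peaks of replicate 1 had a median width of 209 bp and a median enrichment of 3.09, and none reached a −log10 q of 10. The 5158 such peaks of replicate 2 had medians of 244.5 bp and 3.50, and 116 reached it.

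A few genes had domains that depended on the replicate. The highest ratios of replicate 1 to replicate 2 breadth were at C1qtnf5 (10.5), Rhof (7.40) and Mvp (7.31). The lowest were at A930004D18Rik (0.015), Icam4 (0.059) and Gm4969 (0.074). At Rhof the replicate 1 domain spanned 12899 bp and the replicate 2 domain 1743 bp. The Rhof domain of replicate 1 was the one that also held the start of the neighbouring Setd1b, which codes for an H3K4 methyltransferase. At A930004D18Rik the domains were 195 and 13354 bp, and the wider one was shared with Skida1.

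H3K4me3 lay mostly at the starts of protein-coding genes. Of the 21404 replicated peaks on assembled chromosomes, 67.4% (66.8 to 68.0) were within 1 kb of a protein-coding transcript start, and these were wide and strong, with medians of 1703 bp and 38.7-fold enrichment. A further 7.94% were at other annotated starts, 4.72% in exons, 8.58% in introns and 11.4% between genes. Intronic peaks had a median width of 462.5 bp and a median enrichment of 4.50. In the replicate lists, which hold more weak peaks, 58.0% ± 0.648 (SD, n = 2) were at protein-coding starts. The share depended on peak strength, and was 95.04% among the 50% of peaks with the highest enrichment.

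A mark was present at 14061 of the 21853 protein-coding genes, or 64.3% (63.7 to 65.0), against 14148.5 ± 43.1 (SD, n = 2) in the replicate lists. Of the 14061 genes, 63 were not marked in both replicate lists. Promoters rich in CpG were nearly all marked. The share was 98.4% of 11238 genes with high-CpG promoters, 63.9% of 4251 intermediate genes and 4.57% of 6364 low-CpG genes. Domains narrowed in the same order, with median breadths of 2080, 1325 and 953 bp. High-CpG genes had far higher odds of being marked than low-CpG genes (odds ratio 1261, Fisher's exact test, two-sided, p below 1e-300). The median breadth over all marked genes was 1923 bp (1913.5 ± 53.0 in the replicate lists, SD, n = 2).

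The 5 widest domains at protein-coding starts lay over genes for transcription factors. Pou3f3, which codes for a POU-domain factor of neural progenitors, had a domain of 30560 bp on chromosome 1 from 42684103 to 42714662 (30518.5 ± 98.3 bp, SD, n = 2). The nuclear receptor gene Nr2f2 followed with 28309 bp on chromosome 7 from 70343003 to 70371311 (26992.5 ± 2261 bp), and Pou3f2 with 22902 bp on chromosome 4 from 22476479 to 22499380 (22841.5 ± 241 bp). The domain of Otx2, a homeobox gene needed for forebrain and midbrain, spanned 19996 bp on chromosome 14 from 48655098 to 48675093 and covered the whole gene (20272.5 ± 349 bp). Sox2, which codes for a factor that maintains neural progenitors, had 18842 bp on chromosome 3 from 34648022 to 34666863 (18673.5 ± 201.5 bp). Among the 25 widest domains at protein-coding starts were 7 of the midbrain and isthmus genes, namely Otx2, Otx1, Pax3, Pax5, En1, Meis2 and Gata3. There were also 3 of the neural progenitor genes, Sox2, Pax6 and Msi1.

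The remaining widest domains at protein-coding starts lay at Nr2f1, Lhx5, Bahcc1, Irx5, Zfp503, Zic2, Ptch1, Ebf3, Lhx9, Tnrc18, Skida1 and Kdm6b, between 12925 and 16976 bp in breadth. Ptch1 codes for the receptor of Sonic hedgehog, and Kdm6b for a demethylase of H3K27. The domain that held Gata3 was nearest to 4930412O13Rik by the naming rule. It spanned 15085 bp on chromosome 2, but 7255 bp in replicate 1 at that gene against 15161 bp in replicate 2. Meis2 had 13603 bp in the replicated list and 20599 bp in the pooled list. Several of these domains were runs of neighbouring peaks. Without merging, the widest single peak was 18662 bp at Pou3f3, 8766 bp at Nr2f2, 8539 bp at Pou3f2 and 11602 bp at Sox2.

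**Figure D1:**
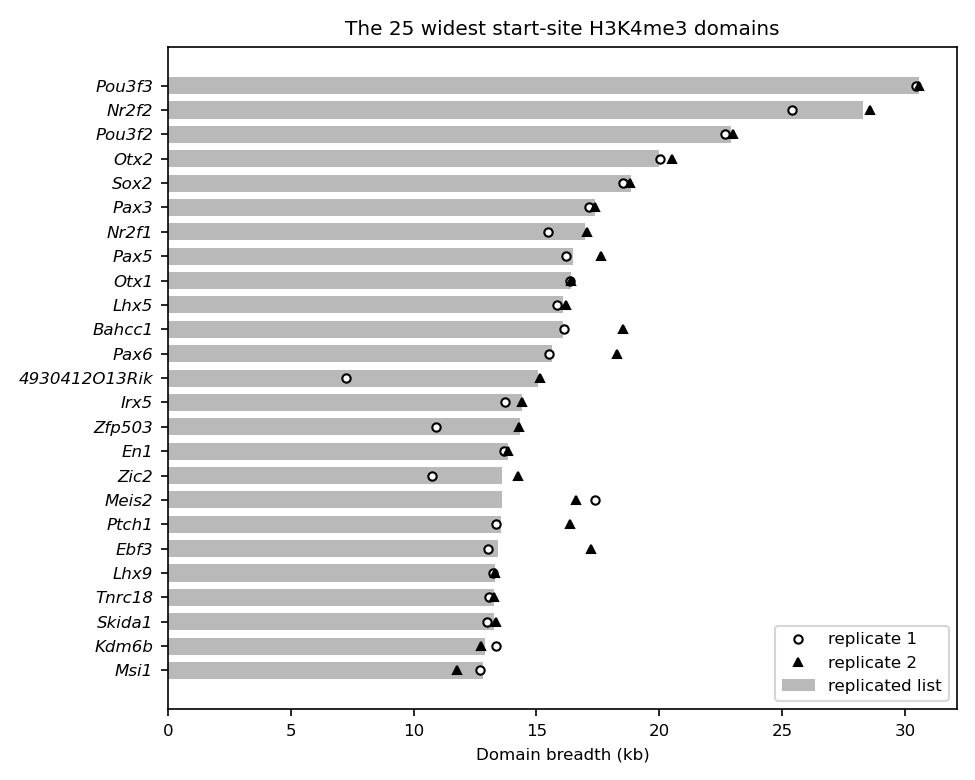
Breadth in kb of the 25 widest H3K4me3 domains at protein-coding starts, with grey bars for the replicated list, open circles for replicate 1 and triangles for replicate 2. The domain at Pou3f3 reached 30560 bp, and that at 4930412O13Rik differed most between the replicates, with 7255 and 15161 bp.

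All 30 genes of midbrain and isthmus patterning were marked, and their domains were wide. Their median breadth was 6823 bp (7264 ± 722 bp, SD, n = 2), which was 3.55 times the 1920 bp of other marked genes. Otx2, En1 and En2, which pattern the midbrain and its boundary with the hindbrain, had 19996, 13832 and 11503 bp. Foxa1, a gene of the ventral midline, had 12140 bp. The marked share was above that of other genes (100% against 64.3%, Fisher's exact test, adjusted p = 7.88e-06), and the domains were wider (permutation test, adjusted p = 2.83e-05). The 50% of peaks with the highest enrichment marked 46.7% of them against 50.7% of other genes (adjusted exact p = 0.717). High-CpG promoters were held by 24 of the 30 genes, and 98.37% of other high-CpG genes were marked. The higher marked share thus does not separate tissue from promoter class.

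Genes of dopaminergic neurons, a cell type of the ventral midbrain, ranged from wide domains to none. En1, Foxa1 and En2 had the widest domains. These genes, with Foxa2, Lmx1a and Lmx1b, belong to the midbrain and isthmus list as well. The breadth results of these lists are thus not independent, and breadth without the shared genes was not tested. No peak was found in any list at Aldh1a1, a retinaldehyde dehydrogenase gene, or at Ddc, which codes for the decarboxylase that makes dopamine. These genes were chosen after their values were seen: Th, for the rate-limiting enzyme of dopamine synthesis, had no peak in the replicated list or either replicate, the dopamine transporter gene Slc6a3 had 849 bp, Pitx3 had 1660 bp and Nr4a2 had 8267 bp. In all, 18 of 21 members were marked, which did not pass the test (adjusted exact p = 0.051). It passed with a 500 bp window (adjusted exact p = 0.0497) and with 5′ gene ends only (adjusted exact p = 0.0319), and in no other setting. The median breadth of 5396 bp was 2.81 times that of other genes (permutation test, adjusted p = 2.83e-05), with 3856.5 bp in replicate 1 and 5746 bp in replicate 2. The difference of 3474 bp was 1980.5 bp without replicate 2 and 1313.5 bp with 5′ gene ends, against 5267.5 bp with gaps of up to 3 kb merged and 6125 bp among high-CpG genes.

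Neural progenitor and early neuron genes were marked without exception. All 24 progenitor genes had a peak, with a median breadth of 6521.5 bp (6325 ± 326 bp, SD, n = 2), and Sox2, Pax6 and Msi1 led them with 18842, 15628 and 12832 bp. All 24 genes of early postmitotic neurons had a peak as well, with a median of 3573 bp (3414.5 ± 275 bp, SD, n = 2). The widest of these were at Scrt1, a neuronal repressor gene, with 7685 bp, Onecut2 with 7624 bp and Onecut1 with 7523 bp. Both lists were above other genes in marked share (adjusted exact p = 9.39e-05 for each) and in breadth (permutation test, adjusted p = 2.83e-05 for each, ratios 3.40 and 1.86). The progenitor and midbrain lists were not tested against each other, and their order turned with 5′ gene ends and without merging, where in the latter they exceeded other genes by 3064.5 and 2761.5 bp. Among the 50% of peaks with the highest enrichment the share call of the neuron list was lost (62.5%, adjusted exact p = 0.362).

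Genes of transmitter identity were marked in 18 of 20 cases (adjusted exact p = 0.0237). The inhibitory genes Slc32a1, for the vesicular GABA transporter, and Gad1, for GABA synthesis, had 9569 and 7776 bp, and the glutamatergic Slc17a6 had 7248 bp. Slc17a8 and Tph2, the latter for serotonin synthesis, had no peak in any list. Their median of 2693 bp was 1.40 times that of other genes (permutation test, adjusted p = 0.00645), but the breadth call was lost without replicate 1 (adjusted p = 0.0631) and at −log10 q of at least 10 (adjusted p = 0.461), and the difference turned to −32.5 bp without merging. The share call was lost at −log10 q of at least 10 (adjusted exact p = 0.0532) and with 5′ gene ends (adjusted exact p = 0.139), and the share was below other genes in the 50% of peaks with the highest enrichment (20%, adjusted exact p = 0.00876).

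Forebrain patterning genes were marked in midbrain too, but by weaker peaks. A peak was found at 22 of 23 members (adjusted exact p = 0.00135), and the 1 without a replicated peak had a peak in another list. Their median breadth was 3645 bp (3225.5 ± 115 bp, SD, n = 2), which was 1.90 times that of other genes (permutation test, adjusted p = 2.83e-05). The widest were at Lhx2 with 9127 bp, Gsx1 with 6772 bp and Six3 with 6694 bp. None of the forebrain genes was marked by the 50% of peaks with the highest enrichment (0% against 50.8% of other genes, adjusted exact p = 3.27e-07). With only peaks of −log10 q of at least 10 the share was 73.9% (adjusted exact p = 0.419), and without merging the difference in breadth was 74 bp (adjusted permutation p = 0.828). The difference between the forebrain and midbrain lists was not tested.

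Hox genes, which pattern the hindbrain and spinal cord, were marked less often than other genes and had narrow domains. Of 39 genes, 15 were marked, or 38.5% (adjusted exact p = 0.0019), although 32 had high-CpG promoters. Their median breadth was 1026 bp, 0.534 times that of other genes (permutation test, adjusted p = 0.00645). The widest were at Hoxd8, 1550 bp on chromosome 2 from 74704554 to 74706103, at Hoxd1 with 1373 bp and at Hoxa1 with 1291 bp, where replicate 1 had 836 bp. Hoxa2 and Hoxa11 had no peak in any list. Peaks covered 8.48% of the Hoxd cluster (8.95% ± 0.509, SD, n = 2), 6.22% of Hoxa (6.01% ± 0.304), 2.52% of Hoxc (2.33% ± 0.361) and 1.80% of Hoxb (1.91% ± 0.566). No Hox peak was among the 50% with the highest enrichment. The call on the share was lost in the pooled list, where 48.7% of Hox genes were marked (adjusted exact p = 0.0588), and with circular shifts that keep neighbouring genes together (adjusted permutation p = 0.096).

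**Figure D2:**
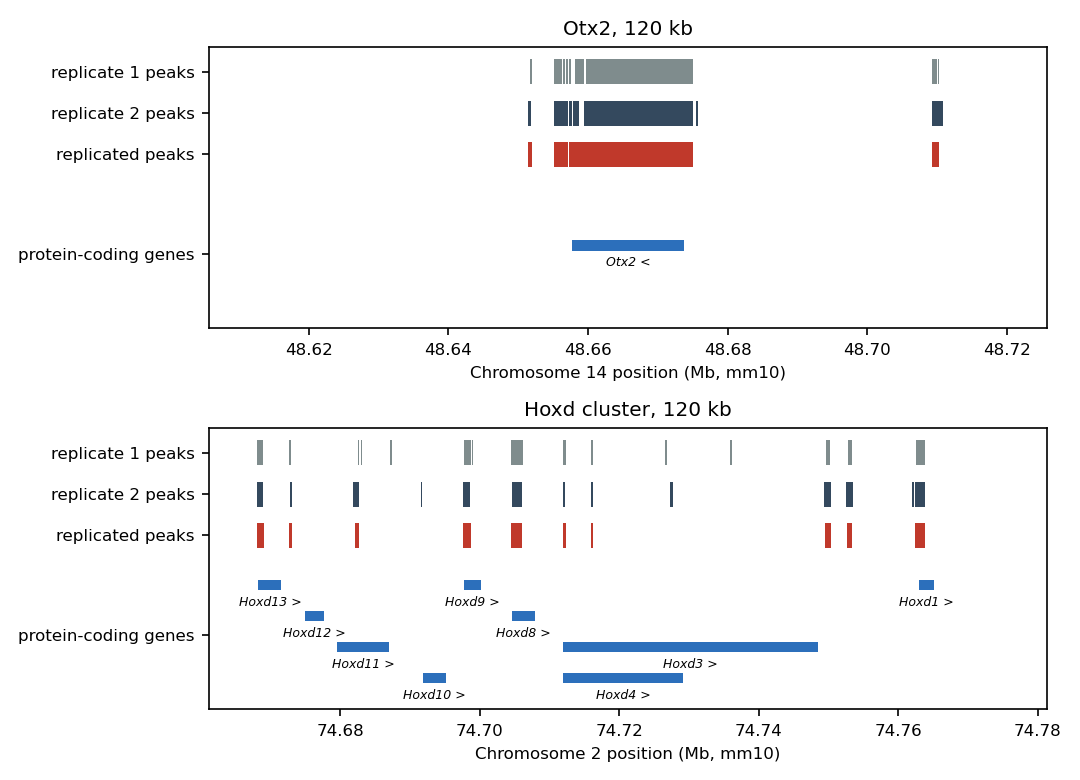
Peaks of replicate 1, replicate 2 and the replicated list, drawn to scale over 120 kb of mm10 around Otx2 on chromosome 14 and the Hoxd cluster on chromosome 2, with protein-coding genes in blue and arrowheads for strand. Peaks at Otx2 merged into a domain of 19996 bp over the whole gene, while 10 separate replicated peaks covered 8.48% of the Hoxd cluster.

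The immune, liver, germline, muscle and erythroid lists were marked less often than other genes. High-CpG promoters were held by 0 of 16 immune, 1 of 19 liver and 2 of 17 erythroid genes. The counts were 4 of 19 for muscle and heart and 6 of 17 for germline. As 4.57% of low-CpG genes were marked, these tests do not separate tissue from promoter class. Among high-CpG genes the liver and erythroid members were all marked. The muscle share was 75% (adjusted exact p = 0.318) and the germline share 16.7% (adjusted exact p = 5.35e-08). Among microglial and immune genes 1 of 16 was marked (adjusted exact p = 6.83e-06). It was Tmem119, with 756 bp (227 and 658 bp in replicates 1 and 2), while Aif1 and C1qa had no peak. Among liver genes 1 of 19 was marked (adjusted exact p = 4.86e-07), which was Apoh with 2493 bp, and Afp and Ahsg had none. Among germline genes 1 of 17 was marked (adjusted exact p = 2.95e-06), which was Dazl with 716 bp, and Ddx4 and Figla had none. Of 19 muscle and heart genes 5 were marked (adjusted exact p = 0.00179), with 1386 bp at Myod1, 906 bp at Des and 793 bp at Tnni3, and none at the actin genes Acta1 and Actc1. Of 17 erythroid genes 6 were marked (adjusted exact p = 0.0254), with 8104 bp at Tal1, 2853 bp at Epor and 1849 bp at Klf1. Gata1 and Alas2 had no peak. The erythroid call was lost in the pooled list (adjusted exact p = 0.0838), without replicate 1 (adjusted exact p = 0.0835), with a 2 kb window (adjusted exact p = 0.087) and with circular shifts (adjusted permutation p = 0.0706).

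The endothelial, mesenchymal, neural crest and glial lists, for other cells that dissected midbrain could hold, did not pass the test of marked share in the replicated list. Endothelial genes were marked in 9 of 16 cases (adjusted exact p = 0.625), with 2078 bp at the vascular receptor gene Flt1, 2054 bp at Sox17 (1154 bp in replicate 1) and 1785 bp at Kdr (2921 bp in replicate 1), and no peak at Pecam1 or Emcn. Mesenchyme and mural genes were marked in 13 of 18 (adjusted exact p = 0.625), with 6256 bp at Foxc1, 5014 bp at Foxd1 and 4351 bp at Pdgfra, and none at Col3a1 or Acta2. Neural crest and placode genes were marked in 13 of 16 (adjusted exact p = 0.232), with 6509 bp at Tfap2a, 4565 bp at Pou4f1 and 3644 bp at Six1, and none at Phox2b or Plp1. Some members of this list, Pou4f1 among them, are also in the midbrain, dopaminergic or neuron lists. Peaks at those members do not point to neural crest cells alone. Glial genes were marked in 10 of 18 (adjusted exact p = 0.505), with 7352 bp at Olig2 (4557 bp in replicate 1), 4351 bp at Pdgfra and 3276 bp at Gja1, and none at Gfap or Aqp4, which are used by mature astrocytes. The breadth of the mesenchymal, neural crest and glial lists did not pass the test (permutation test, adjusted p = 0.169, 0.472 and 0.816), with medians of 2355, 2152 and 1844.5 bp. By the 50% of peaks with the highest enrichment, fewer endothelial (12.5%, adjusted exact p = 0.00328), mesenchymal (16.7%, adjusted exact p = 0.0056) and glial genes (22.2%, adjusted exact p = 0.0228) were marked than other genes. The neural crest difference of 229.5 bp turned to −16.5 bp without replicate 1 and −154 bp without replicate 2.

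Receptor, keratin and protocadherin families were mostly without the mark. High-CpG promoters were held by 1 olfactory receptor, 1 vomeronasal receptor and 3 keratin genes, all of which were marked. Of 1092 olfactory receptor genes 2 were marked (adjusted exact p below 1e-300), Olfr94 with 1123 bp and Olfr658 with 229 bp, which was not marked in replicate 1, and Olfr1 and Olfr10 had none. Of 327 vomeronasal receptor genes 1 was marked, Vmn1r4 with 1972 bp (adjusted exact p = 3.32e-145), and Vmn1r1 and Vmn1r10 had none. In replicate 1 alone 0.917% of the vomeronasal genes were marked. Keratins were marked in 6 of 49 cases (adjusted exact p = 5e-13), with 1705 bp at Krt10, 734 bp at Krt19 and 719 bp at Krt8, and none at Krt1 or Krt12. Clustered protocadherins, which give neurons surface identities, were marked in 13 of 52 cases (adjusted exact p = 6.14e-08) with a median breadth of 564 bp, or 0.293 times that of other genes (permutation test, adjusted p = 0.00102). The widest were at Pcdhga12 with 1985 bp, which was not marked in replicate 1, Pcdhgb7 with 1021 bp and Pcdhga11 with 1010 bp, and Pcdha1 and Pcdha11 had no peak. With circular shifts the protocadherin call on the share was lost (adjusted permutation p = 0.0973).

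**Figure D3:**
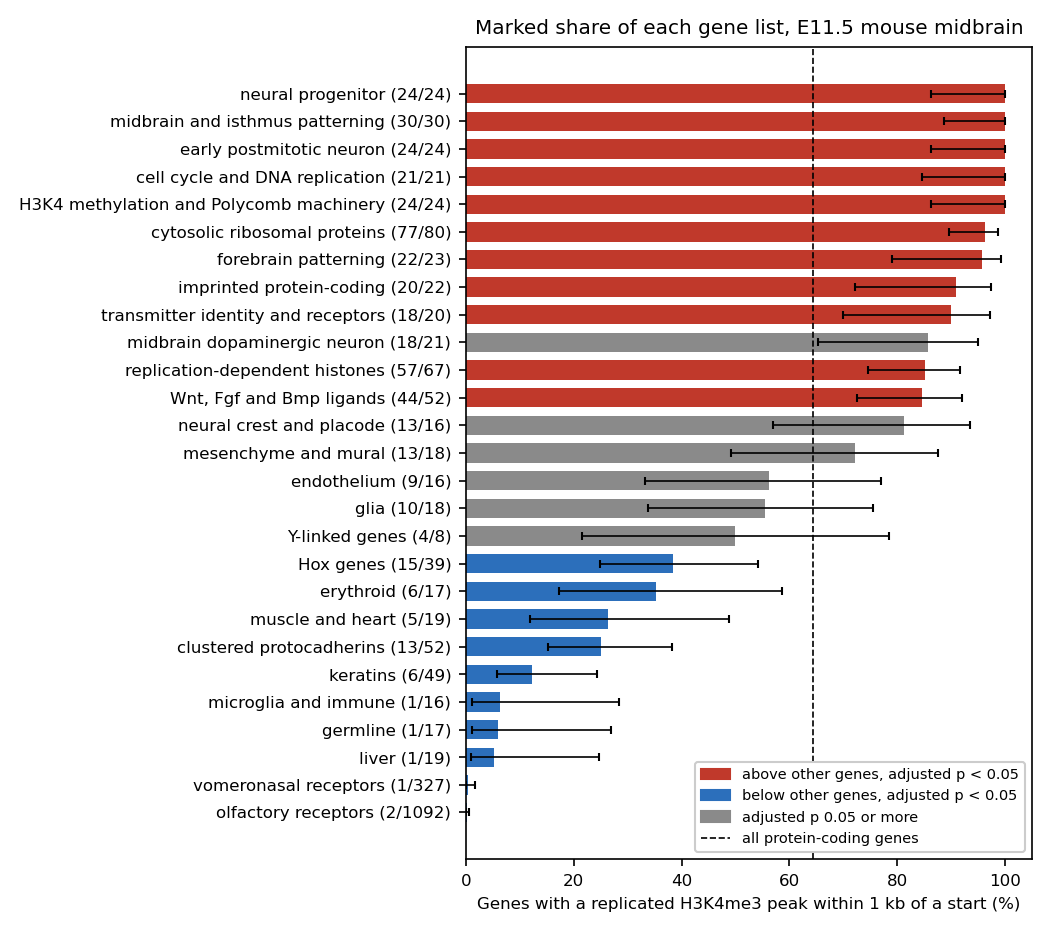
Share in % of each gene list's members with a replicated H3K4me3 peak within 1 kb of a start, with 95% Wilson intervals and the marked and total members in brackets. Lists above other genes are red, those below are blue and those past the threshold in neither direction are grey, and the dashed line is the 64.3% of all protein-coding genes.

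Genes used by every dividing cell were marked almost completely. All 21 cell cycle genes (adjusted exact p = 0.000255) and 77 of 80 ribosomal protein genes (adjusted exact p = 7.31e-11) had a peak. Their domains were wider than those of other genes by ratios of 1.43 and 1.29 (permutation test, adjusted p = 0.00292 and 0.000127). The widest were 4484 bp at Rrm2, 4372 bp at Mki67 and 4088 bp at Plk1, and 6650 bp at Rps18 (6034 and 3559 bp in replicates 1 and 2), 5556 bp at Rps2 and 5516 bp at Rpl18. Rpl10l and Rpl39l, retrogene copies used in testis, had none. All 24 genes of H3K4 methylation and Polycomb proteins were marked (adjusted exact p = 9.39e-05), with a median of 3037.5 bp (ratio 1.58, permutation test, adjusted p = 9.71e-05). Setd1b had 10171 bp, Ring1 9817 bp and Jarid2 5242 bp.

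Histone genes, imprinted genes and signalling ligands were also marked more often than other genes. Replication-dependent histones were marked in 57 of 67 cases (adjusted exact p = 0.000532) with a median of 3032 bp, but their genes sit close together and share domains. Hist1h2af, Hist1h3g and Hist1h4h lay in the same domain of 7316 bp, and Hist1h1t and Hist1h2aa had no peak. Without merging the histone peaks were narrower than those of other genes by a median difference of −336 bp (permutation test, adjusted p = 0.0172), and with circular shifts the share was not past the threshold (adjusted permutation p = 0.215). Among the 50% of peaks with the highest enrichment the histone share was below that of other genes (20.9% against 50.8%, adjusted exact p = 2.61e-06). Imprinted genes were marked in 20 of 22 cases (adjusted exact p = 0.01) with a median of 2878.5 bp (permutation test, adjusted p = 0.00104). Mest had 6239 bp (3906 bp in replicate 1), Peg3 and Usp29 shared a domain of 5551 bp, and Ndn and Rtl1 had no peak. The imprinted call on the share was lost with 5′ gene ends (adjusted exact p = 0.23), among the 50% of peaks with the highest enrichment (59.09%, adjusted exact p = 0.544) and with circular shifts (adjusted permutation p = 0.0661), and the breadth call was lost with 5′ gene ends too (adjusted permutation p = 0.173). Wnt, Fgf and Bmp genes were marked in 44 of 52 cases (adjusted exact p = 0.00301) with a median of 2364 bp (ratio 1.23, permutation test, adjusted p = 0.0103), which without merging was not past the threshold (adjusted p = 0.592). Their share call was lost at −log10 q of at least 10 (76.9%, adjusted exact p = 0.0556) and turned among the 50% of peaks with the highest enrichment (44.2% against 50.7%, adjusted exact p = 0.456). Wnt5a had 9412 bp, Wnt7b 7310 bp and Fgf9 6972 bp, and Bmp10 and Bmp15 had none.

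Of the 27 lists, 11 were above other genes in marked share, 10 were below and 6 did not pass the test. The counts were 4 above and 17 below among the 50% of peaks with the highest enrichment, and 9 above and 7 below with circular shifts, which keep neighbouring genes together. Among high-CpG genes nearly all are marked, so no list could pass as above the rest. The 11 calls above other genes thus do not separate tissue from promoter class. Below the rest among high-CpG genes were 4 lists, namely Hox genes, germline genes, protocadherins and histones. Breadth set lists apart within high-CpG genes too, where 11 of the 14 lists with enough members were wider and 1 was narrower. Across all marked genes 12 of 17 lists were wider and 2 narrower, against 8 wider and 3 narrower without merging, where the histone list turned narrower.

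**Figure D4:**
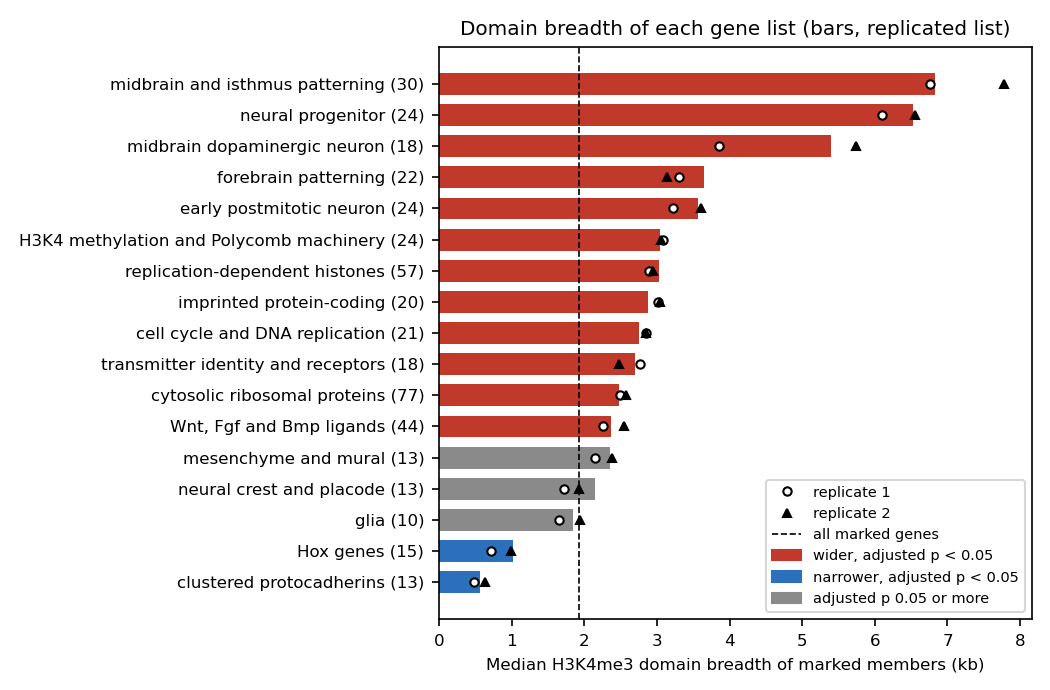
Median breadth in kb of the marked members of the 17 gene lists tested, with bars for the replicated list, open circles for replicate 1, triangles for replicate 2, the number of marked members in brackets and a dashed line at 1923 bp for all marked genes. Medians of the replicated list range from 564 bp for clustered protocadherins to 6521.5 bp for neural progenitor and 6823 bp for midbrain genes.

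Wide domains also lay far from protein-coding starts. The widest, 23597 bp on chromosome 13 from 83718329 to 83741925, was 65441 bp from the nearest such start, at Mef2c, and overlapped the long noncoding RNA gene C130071C03Rik (25922 ± 3495 bp, SD, n = 2). The next spanned 13553 bp on chromosome 3 from 17783667 to 17797219 over Mir124-2hg, a host gene of the neuronal microRNA miR-124. A domain of 12963 bp on chromosome 12 from 117148268 to 117161230 lay inside Ptprn2 and overlapped Gm10421. Another of 12101 bp on chromosome 7 from 79498867 to 79510967 lay 32505 bp from Polg and overlapped the microRNA gene Mir9-3. The last, 10831 bp on chromosome 13 from 78174867 to 78185697, lay next to Nr2f1 over 3110006O06Rik, and joined the Nr2f1 domain when gaps of up to 3 kb were merged (33932 bp).

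Most distal peaks were weaker and less often shared. Replicated peaks beyond 5 kb of any annotated start numbered 2810, or 13.1%, with a median width of 586.5 bp against 1624 bp within 1 kb. In replicate 1, 65.1% of distal peaks were overlapped by replicate 2, against 93.1% of peaks within 1 kb of a start (odds ratio 7.26, Fisher's exact test, two-sided, p below 1e-300). In replicate 2 the shares were 59.8% and 91.3% (odds ratio 7.10, p below 1e-300). With only peaks of −log10 q of at least 10, the shares were 98.68% and 99.85% in replicate 1. In replicate 2 they were 59.13% and 94.02% under that filter. Distal peaks were narrower, with medians of 286 and 411 bp in replicates 1 and 2, against 1293 and 1517 bp within 1 kb. The shares were not matched for width, which bears on an overlap of at least 1 bp.

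Genes on the X chromosome were marked less often than autosomal genes. The share was 50.2% of 948 X-linked genes against 65.5% of 20722 autosomal genes (odds ratio 0.530, Fisher's exact test, two-sided, p = 4.06e-21). The odds ratio was 0.432 without receptor genes, which left 941 X-linked and 19310 autosomal genes. Among genes whose start sequence was not shared with another gene, and within CpG classes, the pooled odds ratio was 1.16 (0.926 to 1.46), but it was 0.370 in the high, 1.08 in the intermediate and 2.13 in the low-CpG class. The tissue came from both sexes, and genes specific to either were marked. Xist, the RNA gene that silences 1 X chromosome in females, had a domain of 3689 bp on the X chromosome from 103480364 to 103484052 (3341 and 3841 bp in the replicates). Of 183 Y-linked genes 4 were marked, all from the fixed list of 8 (adjusted exact p = 0.505 for that list). They were Eif2s3y with 1469 bp (842 bp in replicate 1), Ddx3y with 1293 bp, Uty with 1182 bp and Kdm5d with 1058 bp. Usp9y, Zfy1, Zfy2 and Sry were not marked in the replicated list.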

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

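The tests of CpG content together with shared sequence, pooled and by class, and of shared sequence at Hox genes alone, were chosen after the results of the other tests of those patterns were seen, and the rule for reading the first of these was changed after its own values were seen. Comparisons by position and gene used only the assembled chromosomes, but 10 further replicated peaks lay on 5 unplaced or unlocalized scaffolds, all of them overlapped in both replicate lists, with widths of 245 to 2026 bp and enrichments of 2.32 to 46.2. Of these, 4 were on scaffolds assigned to the X chromosome, 3 on scaffolds assigned to chromosome 4 and 3 on unplaced scaffolds.

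Wide domains marked the genes of the midbrain, dopaminergic, forebrain and progenitor lists together. The 88 marked genes had a median breadth of 4955.5 bp against 1919 bp for other marked genes, a ratio of 2.58. The tables argue against promoter CpG class, the number of annotated starts and the merging of peaks, each as the whole cause. The ratio was 2.75 among high-CpG genes. It was 2.45 with 1 start per gene against 10000 draws matched on annotated starts, where 6 or more starts were treated alike. For the widest single peaks without merging it was 1.91. The CpG class rests on 500 bp windows within 1 kb of a start, so the extent of CpG-rich sequence across wide domains was not tested. Each of these was past its permutation test (p = 1e-05, 0.0001 and 1e-05, the smallest these can give), although without merging the forebrain list alone differed by 74 bp (adjusted permutation p = 0.828). With 1 tissue and 1 stage, no biological explanation was tested, so it stays open whether wide domains at these genes may go with their use in this tissue.

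The lower marked share on the X chromosome was kept when genes of shared start sequence alone were left out (odds ratio 0.729, 95% interval 0.629 to 0.845). The tables thus argue against shared start sequence alone as the whole cause. With CpG class alone held fixed the pooled ratio was also below 1 (Mantel-Haenszel odds ratio 0.703, interval 0.577 to 0.855). The classes went both ways, however, with 0.586 (0.469 to 0.731) in the intermediate and 1.68 (1.09 to 2.59) in the low-CpG class. By the rule set beforehand, an upper bound below 1 counts against CpG class alone as the whole cause. As the classes went both ways, that reading is kept here for the intermediate class only. There 52.48% of X-linked genes were marked against 65.35% of autosomal genes, which argues against CpG class alone as the cause in that class. With CpG class and shared start sequence together the pooled odds ratio was 1.16 (0.926 to 1.46). The ratios again differed between classes, at 0.370 (0.170 to 0.802) in the high, 1.08 (0.823 to 1.41) in the intermediate and 2.13 (1.37 to 3.31) in the low-CpG class. A pooled value over classes that go both ways decides nothing, so whether both together explain the lower share stays open. The rule first written, by the pooled interval alone, would count both together as fitting, and a rule by which any class with an interval below 1 excludes them, also tried, would count them as not fitting. How reads were mapped at shared starts was not analysed here, and 7 of the 177 X-linked genes with one were marked. Start sequence was shared at 18.7% of X-linked and 4.01% of autosomal genes, and at 92.4% of Y-linked genes, none of which was marked when shared. The odds ratio with all genes was 0.549 in the high, 0.586 in the intermediate and 1.68 in the low-CpG class, so a single pooled ratio does not describe all classes. No biological explanation, such as X inactivation in female cells, was tested.

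Of the 11238 genes with high-CpG promoters, 183 had no replicated peak, and 17 of these were Hox genes. Weak peaks lost by the replication rule are argued against as the main cause, since 13.7% of the 183 had a peak in another list (interval 9.43 to 19.4). Shared start sequence stays open for the whole set, at 38.8% (32.0 to 46.0) against 0.344% of marked high-CpG genes. For the Hox genes it is argued against, at 0% of the 17 (upper bound 18.4%). Across all lists, 6 of the 42 high-CpG members without a peak had a shared start region. The other lists, histones among them, were not tested alone. No biological explanation, such as Polycomb silencing of Hox genes, was tested, and other repressive marks were not analysed here.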

How the results depend on the processing

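The number of marked genes (11082 to 14207) stayed within 1.5 times its value. The odds ratios for CpG class, the X chromosome and distal peaks kept direction and significance under the changes of list, threshold, window, start, distance, overlap and receptor genes tried for them, but in the upper 50% by enrichment the CpG ratio was 683.7 in place of 1261 and the X chromosome ratio 0.3001 in place of 0.530. The X chromosome ratio did not keep them when CpG class and shared start sequence were both accounted for (1.16), nor within high-CpG (0.549, interval 0.267 to 1.13) or low-CpG genes (1.68). Of 268 marked shares of lists under alternatives 220 kept their direction and side of the threshold, as did 157 of 172 breadth differences. The causes of the changes below were not tested, except where a setting removes peaks, genes or merging by construction. No paired analysis was possible because there is 1 group. Read depth is unknown, so a missing peak at weakly marked genes such as Hox genes sets no bound on the mark.

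The share of peaks at protein-coding starts was 61.9% in the pooled list, 57.5% to 58.4% without either replicate, 79.1% at −log10 q of at least 10, 95.04% in the upper 50% by enrichment, 65.4% with a 500 bp window, 71.6% with 2 kb and 58.7% with 5′ gene ends. Overlap of replicate 1 peaks in replicate 2, and the reverse, was 64.8% and 70.5% when 50% of both peaks had to overlap, 99.7% and 88.7% at −log10 q of at least 10, 86.6% and 78.5% with equal numbers of top peaks, and 85.9% and 87.7% after merging. The rank correlation of enrichment was 0.971 with 50% overlap and 0.904 at −log10 q of at least 10.

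Coverage of Hoxa and Hoxd was 6.63% and 9.14% in the pooled list. Without either replicate it was 5.79% to 6.22% for Hoxa, 1.51% to 2.31% for Hoxb, 2.07% to 2.58% for Hoxc and 8.59% to 9.31% for Hoxd. At −log10 q of at least 10 it was 4.39%, 0.770%, 0.384% and 5.82% for Hoxa, Hoxb, Hoxc and Hoxd, and in the upper 50% by enrichment 0% for each.

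The number of lists past the threshold in marked share was 4 among high-CpG genes, with 4 below and 0 above, which the 98.37% of other such genes marked allowed for no list, and 21 in the upper 50% by enrichment, with 4 above and 17 below in place of 11 and 10. Under that filter the direction turned for midbrain (46.7%), dopaminergic (42.9%), forebrain (0%), transmitter (20%), mesenchyme (16.7%), neural crest (25%), histone (20.9%) and ligand genes (44.2%). Among high-CpG genes it turned for forebrain (95.5%), endothelium (100%), erythroid (100%), neural crest (92.3%), liver (100%), olfactory (100%), vomeronasal (100%), keratin (100%) and histone genes (87.5%), often with few members left. Circular shifts left 16 calls, 9 above and 7 below, losing Hox, erythroid (adjusted permutation p = 0.0706), protocadherin, histone and imprinted genes. The erythroid call was also lost with a 2 kb window (adjusted exact p = 0.087).

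The number of lists past the threshold in breadth was 8 in the upper 50% by enrichment, where 9 lists could be tested. The neural crest difference, which passed no test, was −16.5 bp and −154 bp without replicates 1 and 2, −189 bp at −log10 q of at least 10, −105 bp with 5′ gene ends, −122 bp without merging and −58.5 bp among high-CpG genes. Without merging, the transmitter difference was −32.5 bp and the histone difference −336 bp. The breadth call was lost for histones in the upper 50% by enrichment (adjusted permutation p = 0.0537) and for ligands among high-CpG genes (adjusted permutation p = 0.234). Of 100 named domains, breadth moved by over 1.5 times in 50 without merging, 12 with a 3 kb gap, 2 in the pooled list and 4 without replicate 1, in 13 of 98 without replicate 2, 11 of 91 at −log10 q of at least 10 and 20 of 57 in the upper 50% by enrichment.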

Other observations

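The microRNA tests and the genes named here were chosen after the widest distal domains and the values of those genes were seen. Several of the widest distal domains lay over microRNA genes. Mir9-2 lay in the widest distal domain, by Mef2c, Mir124a-2 in the next and Mir9-3 in the fourth. The next such domains by width were 8634 bp at Mir124a-3, 7589 bp at Mir124a-1 and Mir3078, 7494 bp at Mir125b-1, 5968 bp at Mir1897, 5374 bp at Mir137 and Gm24155, 4126 bp at Mirlet7i, and 3965 bp at Mir9-1, Mir3093 and Gm25641. In all, 36 of 4189 distal domains, those more than 5 kb from a protein-coding start, overlapped an annotated microRNA gene. Noncoding genes far from coding starts were marked at 7.85% of 5188 long intergenic RNA genes and 4.01% of 1670 microRNA genes, against 0.988% of 9109 processed pseudogenes.

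Breadth and enrichment ranked genes differently, with a Spearman rho of 0.492 across 14061 marked genes. The upper 50% of peaks by enrichment held a start-site peak of 78.8% of marked genes. This share was 100% for the 24 H3K4 methylation and Polycomb genes and 97.4% for ribosomal protein genes, but 46.7% for midbrain patterning genes, 0% for the 22 marked forebrain genes and 0% for the 15 marked Hox genes. Midbrain patterning genes had a median breadth of 6823 bp, at a median enrichment percentile of 46.95 among peaks. Germline genes were the high-CpG genes most often without a peak among lists with at least 5 such members, at 5 of 6, followed by protocadherins at 8 of 14 and Hox genes at 17 of 32. Sycp1, Spo11, Stra8 and Tex11, all genes of meiosis, had high-CpG promoters and no replicated peak.

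It was tested as a hypothesis whether distal domains over microRNA genes are wider than others. Leaving out the 5 widest domains from which the idea came, the 33 others had a median width of 1748 bp against 682 bp for distal domains without a microRNA gene, a ratio of 2.56 (permutation test, p = 1e-05, the smallest it can give). A wide domain overlaps more genes by chance, which might produce this. Domains drawn in proportion to their width had a median of 1092 bp. The observed median was 1.60 times that, with a share of 0.002 of 10000 draws as wide. This argues against overlap by width alone. The draws were not matched for lying at an annotated start, however. Replicated peaks at other annotated starts had a median width of 765 bp, against 462.5 bp in introns and 591 bp between genes. The tests thus cannot tell microRNA genes from other noncoding genes. Neither test says why the domains are wide, and expression of these microRNAs was not analysed here.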
